A study of Mus musculus with 2 samples.

How the data were processed

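The data are ATAC-seq peak lists of 2 libraries of sorted fetal thymic progenitors, 1 wild-type and 1 E2A and HEB double knockout, grouped by the genotype in the labels. Bcl2fastq 1.8.4, Bowtie and HOMER, and the mouse build mm9, are named per the submitters' processing notes, without roles or settings; a Bowtie version given there is left out because its number may be garbled. Whether read ends were shifted for the transposase, how duplicate and mitochondrial reads were treated, whether a background library was used and at which threshold peaks were called are not given in the sources used here. Each of these choices, like the depth, could change the length of a list.

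Each deposited file holds 1 library, so the authors called peaks per sample. It gives the chromosome, start, end, name, score and strand of each peak. The authors' score is in a column without a header, and its unit is not given in the sources used here. It is positive, and scores below 9 fall on whole multiples of 0.10952 in the wild type and 0.106168 in the double knockout, with a largest deviation of 0.00496 in both, and the lowest scores are 23 and 24 such steps. What 1 step stands for is not stated, so no counts were derived from it. The score was used only to rank and filter peaks within a list. Peak names carry a running number per chromosome, and the listed peaks are 76.6% of the highest numbers in the wild type and 75.8% in the double knockout, so the numbering has gaps in both. All peaks are 151 bp wide except 1 per list at the end of chromosome 2 (116 and 114 bp), and starts within a list are at least 300 bp apart. A fixed width means that 1 broad accessible region can be marked at different places in the lists.

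Coordinates are mm9, given 1-based. The gene table at hand is of another build (GRCm38): 5.86% of its protein-coding gene ends had a wild-type peak within 500 bp, against 5.33% after moving the ends by 137 kb. Coordinates were not converted, so peaks carry no gene names here, and the planned counts at listed lymphoid, progenitor, myeloid, erythroid and stromal genes, at transcription starts and of sequence motifs were not run.

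A peak was shared if it overlapped a peak of the other list by at least 1 bp (bedtools 2.31.1 intersect), and otherwise library-only. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only and treat peaks as independent, which neighbouring peaks are not. Background overlap was measured by moving 1 list along the genome by 10 to 100 kb. Library-only peaks were assigned by their centre to 200 kb windows, and the 5 windows with the largest excess per library, ties included, are named, by a rule set before the data were examined. The excess was set beside 10000 random reassignments of the library-only labels within each chromosome (1000 for the alternatives), as a description of these libraries and not a test of the genotypes. The joined stretches, the 2 Mb windows and the isolated strong peaks were added after the data were seen. For the stretches, limits of 5 and then 4 on the excess were tried. For the isolated peaks, 12 combinations were viewed: distances of 1, 5 and 10 kb to the other list, each with the strongest 50, 30, 20 and 10% of a list. Alternatives covered the overlap rule, the score threshold, list length, peak width, chromosomes, merging of close peaks, and window size and position. The calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3.

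The overlap and window steps were run on simulated data made from the wild-type list. With 59.85% of its 85764 peaks copied to a second list with small shifts, 59.85% were found as shared. The shifts were always shorter than a peak, so this share was fixed in advance and checks only the running of the step. Of 20 windows planted with 12 extra peaks, 19 were among the 25 with the largest excess. The simulated second list held no other library-only peaks, so this does not show how such windows would rank in the real lists.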

Results

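Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in early thymic progenitors (ETPs) of the mouse fetal thymus. ETPs are the most immature cells of the thymus that can still enter the T cell lineage, and were sorted as lineage-negative, CD4-negative, CD8-negative, CD44-positive, CD25-negative and Kit-positive cells. There were 2 libraries. The first came from wild-type animals on the C57BL/6 background. The second came from animals with floxed alleles of the E protein genes E2A and HEB and the IL7R-Cre driver, referred to here as the double knockout. E2A and HEB are basic helix-loop-helix transcription factors that bind E-box sequences. The double-knockout cells were sorted with YFP as a further marker, which the wild-type sort did not use. With 1 library per genotype there was no replicate check on any difference, no test between genotypes was made, and intervals cover counting error over peaks only.

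The deposited values were 1 list of accessible regions (peaks) per library, with a score for each peak. The wild-type list held 85764 peaks and the double-knockout list 69896. Nearly every peak was 151 bp wide, so that the lists covered 12950 kb and 10554 kb of the mm9 genome. The read depth behind the lists is unknown. The median score was 7.99 in the wild type and 7.96 in the double knockout.

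The first comparison asked which accessible regions of wild-type ETPs were found again in the double knockout. Loss of E2A and HEB in these cells was not checked here. A total of 52206 regions were called in both genotypes. They made up 60.9% of the wild-type peaks (exact 95% interval 60.5 to 61.2%) and 74.7% of the double-knockout peaks (74.4 to 75.0%). When the double-knockout list was moved along the genome by 10 to 100 kb, only 1.42 to 1.78% of the wild-type peaks overlapped it. The centres of shared peaks lay close together, with a median distance of 10 bp. A further 33558 regions were called in the wild type alone and 17690 in the double knockout alone, so that wild-type-only regions made up 65.5% of the regions found in a single library. Because each shared peak had 1 partner, the difference between these counts, 15868, equals the difference in list length and carries no further information. Counting peaks up to 500 bp apart as shared left 28060 wild-type-only and 11465 double-knockout-only regions.

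Library-only regions were mostly of low score within their own list. In the wild type their median score was 5.26 (quartiles 3.94 and 8.1), against 10.7 (6.57 and 19.7) for shared regions. In the double knockout the medians were 5.31 (3.82 and 8.81) and 9.34 (5.41 and 19.4). Of the strongest 10% of each list, 93.4% of the wild-type and 93.8% of the double-knockout peaks overlapped a peak of any score in the other list. In the weakest 10% the shared part was 23.4% (22.5 to 24.3%) of the wild-type and 50.5% (49.3 to 51.7%) of the double-knockout peaks. This holds against the whole other list, weak peaks included: when both lists were cut to their upper 50% by score, 61.2% of the wild-type and 75.1% of the double-knockout peaks were shared, close to the values for the whole lists. With 500 bp of tolerance, 73 of the 8577 strongest wild-type peaks and 19 of the 6990 strongest double-knockout peaks had no counterpart.

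**Figure D1:**
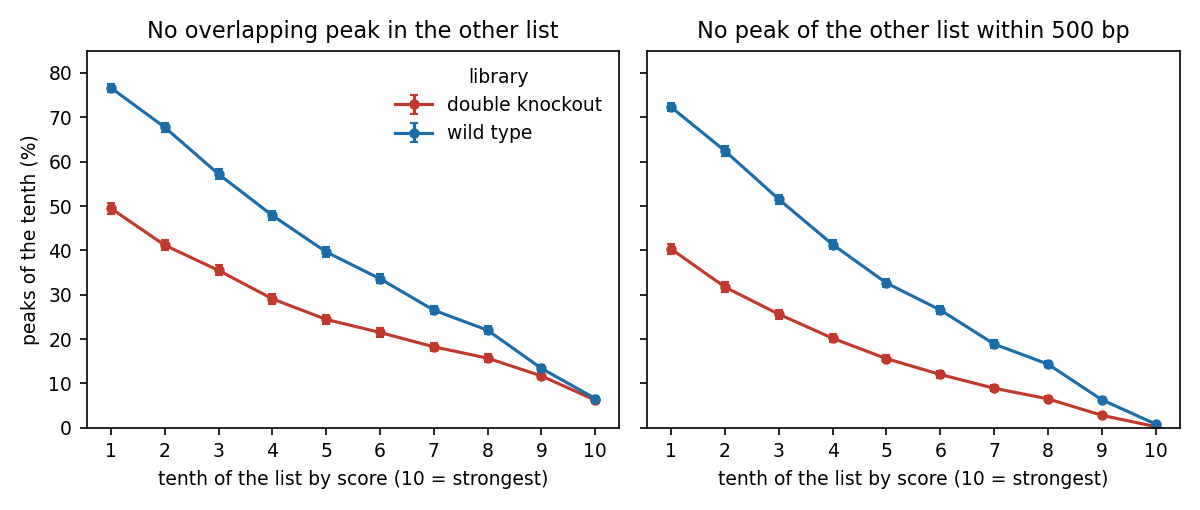
Percentage of peaks with no overlapping peak in the other list (left) or with no peak of the other list within 500 bp (right), in each of 10 equal parts of a list ranked by score, for the wild-type (blue) and double-knockout (red) libraries; bars are exact 95% binomial intervals and cover counting error only. In the left panel the percentage without a partner fell from 76.6% to 6.61% in the wild type and from 49.5% to 6.24% in the double knockout between the weakest and the strongest part.

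The surplus of wild-type regions was spread over the genome. Each of the 19 autosomes held fewer double-knockout than wild-type peaks, with 0.815 double-knockout peaks per wild-type peak over all chromosomes. The X chromosome held 2.42% of the peaks in both lists. Chromosome 13 was shifted most towards the wild type, with wild-type-only peaks making up 69.4% of its library-only peaks (67.6 to 71.2%), followed by chromosome 1 at 68.2% (66.7 to 69.6%) and chromosome 16 at 67.8% (65.5 to 69.9%). Chromosome 11 was shifted least, at 61.2% (59.4 to 62.9%), and chromosome 17 stood at 62.9% (60.8 to 64.9%). The intervals of these 5 among the 20 chromosomes compared excluded the overall 65.5%. At equal list lengths, where the overall share is 50% by construction, it was 53.7% on chromosome 13 and 44.7% on chromosome 11, so that double-knockout-only peaks were then the larger part on chromosome 11. Chromosome Y carried 10 wild-type peaks and none in the double knockout.

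**Figure D2:**
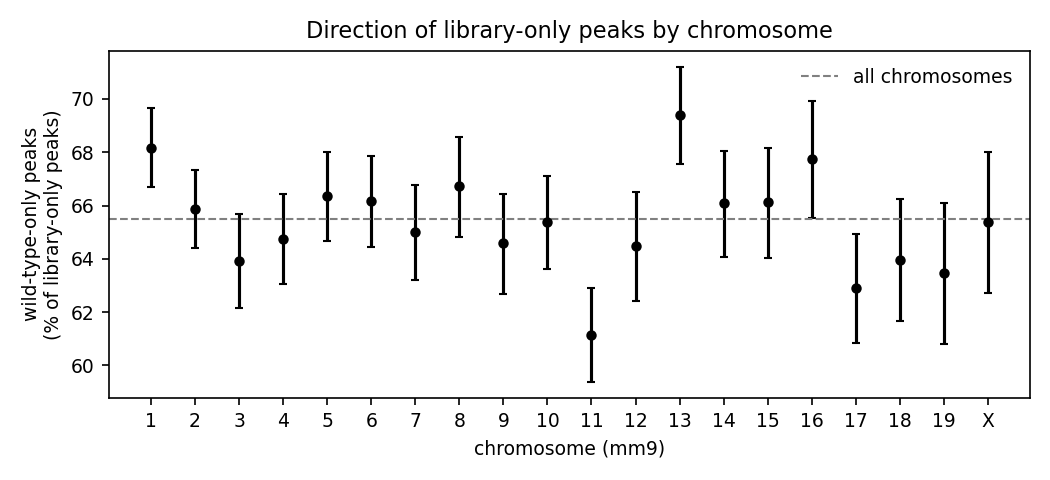
Wild-type-only peaks as a percentage of all library-only peaks on each autosome and the X chromosome, with exact 95% binomial intervals; the dashed line marks 65.5%, the value over all chromosomes, and the axis does not start at 0. Chromosome 13 lies highest at 69.4% and chromosome 11 lowest at 61.2%.

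Regions that lost or gained several accessible sites together were sought in windows of 200 kb. Of 9449 windows with a library-only peak, 6767 held more wild-type-only and 1632 more double-knockout-only peaks. A split in this direction follows from the longer wild-type list, with 33558 against 17690 library-only peaks. It was not counted at equal list lengths and is no measure of local loss. The window with the largest double-knockout excess was on the X chromosome (47800001 to 48000000), with 23 double-knockout-only peaks and no wild-type-only peak. Those 23 peaks formed an array of 73.2 kb (47903083 to 47976321) with a median spacing of 2.77 kb, no wild-type peak between them and a median score of 19.9, at percentile 79.9 of the double-knockout list. None of 10000 random reassignments of the library-only labels within chromosomes gave an excess of 23 (highest 14). The double-knockout list also held none of the 10 Y peaks of the wild type. At this array, a difference in sex between the libraries therefore cannot be told apart from one of genotype. The next double-knockout windows were on chromosome 12 (74600001 to 74800000), with 17 double-knockout-only against 6 wild-type-only peaks, on chromosome 12 (108200001 to 108400000), with 10 against 0, and on chromosome 4 (133800001 to 134000000), with 12 against 2. The fifth place was shared by a window on chromosome 1 (90400001 to 90600000), with 14 against 5, and another on chromosome 3 (78800001 to 79000000), with 12 against 3.

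In the wild-type direction, 3 of the 5 leading windows lay close together on chromosome 14. The window from 69800001 to 70000000 held 17 wild-type-only peaks and no double-knockout-only peak, while those from 70200001 to 70400000 and from 70600001 to 70800000 each held 14 and 0. The other 2 leading windows were on chromosome 15 (25400001 to 25600000) and on chromosome 5 (100600001 to 100800000), each with 16 against 2. How unusual this excess was depended on the setting: 3483 of the 10000 reassignments gave one of 17 or more in the 200 kb windows as planned, 3 of 1000 gave one as large at equal list lengths, where it was also 17, and 16 of 1000 did so with windows shifted by 100 kb, where it was 20. With gaps of up to 500 bp counted as shared, 79 of 1000 reached 17, and in 100 kb windows 999 of 1000 reached the excess of 10 found there. In windows of 500 kb, the chromosome 14 excess was 34 (69500001 to 70000000), which 3 of 1000 reassignments reached.

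Adjacent windows with an excess of at least 4, a limit chosen after the data were seen and after a limit of 5 had been tried, joined into longer stretches. The longest wild-type stretch covered 2.6 Mb of chromosome 14 (69200001 to 71800000). It held 139 wild-type-only, 18 double-knockout-only and, over all classes, 177 wild-type and 56 double-knockout peaks. This is 6.81 wild-type peaks per 100 kb against 3.25 over the genome, and 2.15 double-knockout peaks against 2.64. The longest double-knockout stretch covered 1.2 Mb of chromosome 12 (108000001 to 109200000). All 13 wild-type peaks there were shared, and 42 of the 55 double-knockout peaks were not, with a low median score of 4.78. Reassigned labels gave a stretch of 13 windows, as on chromosome 14, in 19 of 10000 draws, and never one of 6 windows in the double-knockout direction, as on chromosome 12. With the limit of 5 tried before, the chromosome 14 stretch shortened to 8 windows, which 450 of 10000 draws reached, and the chromosome 12 stretch to 3 windows, which 6 reached. In windows of 2 Mb, also added after the data were seen, chromosome 12 led the double-knockout direction with 56 against 17 peaks (108000001 to 110000000), and the X array was no longer the leading region.

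**Figure D3:**
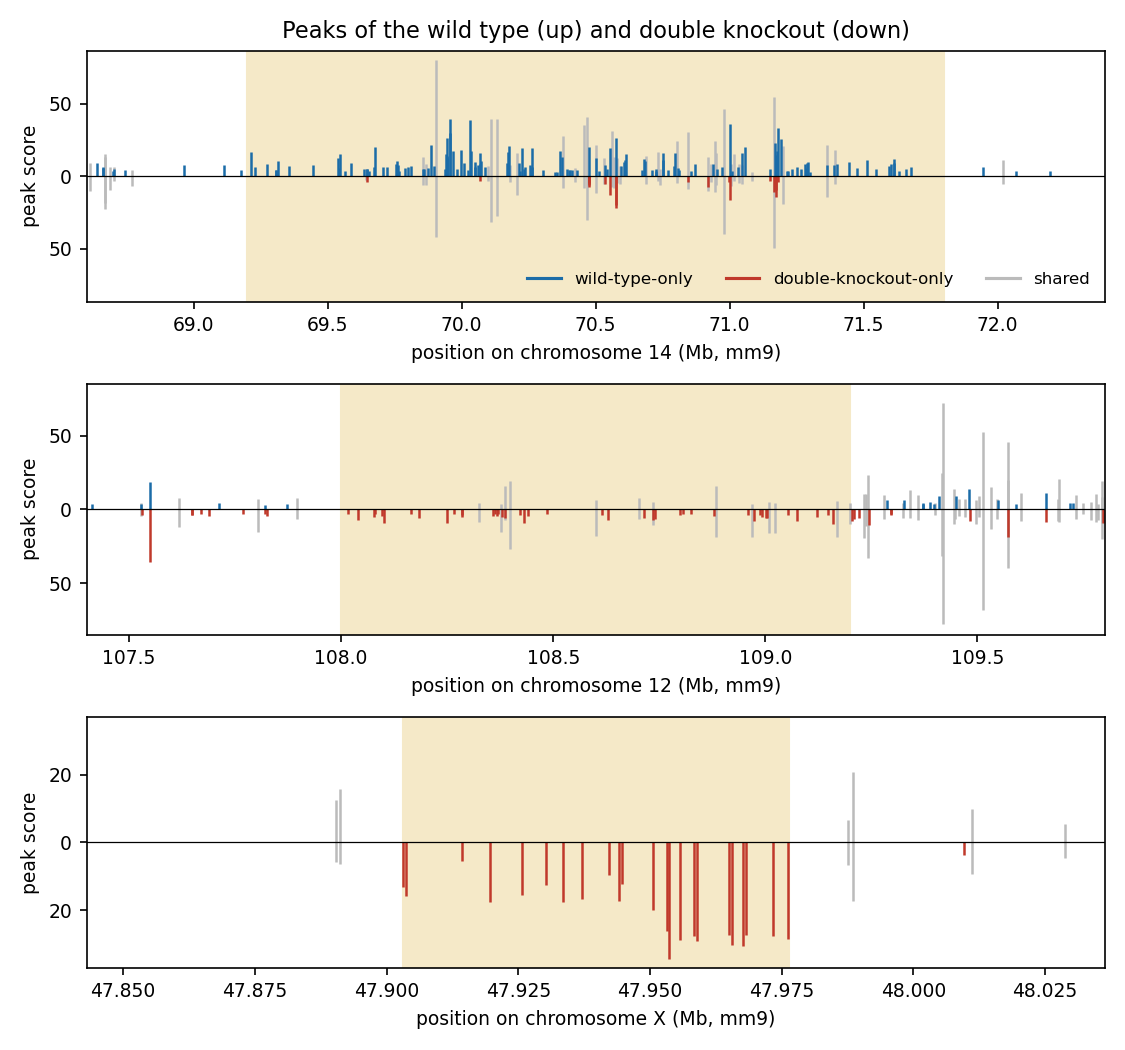
Peaks along the wild-type stretch on chromosome 14, the double-knockout stretch on chromosome 12 and the X array (shaded), as lines at the peak centre whose length is the peak's score in its own list, upwards for the wild type and downwards for the double knockout; blue and red lines are wild-type-only and double-knockout-only peaks and grey lines are shared, and scores of the 2 lists are not on a common scale. The array on the X holds 23 double-knockout-only peaks and no wild-type peak.

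Strong regions with no peak of the other list within 5 kb were rare. In the strongest 20% of each list, 140 wild-type peaks (0.816%) and 21 double-knockout peaks (0.150%) had no peak of the other genotype within 5 kb. Both limits were chosen after 12 combinations of distance and score had been viewed. By overlap alone, 6.61% of the strongest 10% of wild-type peaks and 6.24% of those of the double knockout had no partner. The wild-type list is longer, so the counts of 140 and 21 are not directly comparable. The strongest 2 of the wild-type set, with scores of 39.4 and 38.6, lay on chromosome 14 (69955204 to 69955354 and 70029262 to 70029412), and 15 of the 140 fell into the stretch described above. That stretch was chosen for its excess of wild-type-only peaks, so isolated wild-type peaks inside it are no separate evidence. None of the 140 was on the X chromosome and 3 were on the Y. The X counts depended strongly on the limits. With the strongest 10% and 1 kb, the combination tried first, 2 of 10 isolated double-knockout peaks and none of 63 isolated wild-type peaks were on the X, and with the strongest 50% and 1 kb these were 57 of 1679 and 80 of 5197. Of the 21 double-knockout peaks, 17 were on the X: 11 in the array and 6 between 72975237 and 72995890, where the wild-type list held no peak. Sex and genotype cannot be told apart for these X peaks either. The strongest of the 17, with a score of 36.8, lay at 72989890 to 72990040. The 4 others were on autosomes, led by a peak on chromosome 11 (58143796 to 58143946) with a score of 31.3.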

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

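No paired analysis was possible because there was 1 library per genotype, and no replicate could be left out. Which library had more library-only peaks follows from list length wherever shared peaks pair 1 to 1, so that its direction says nothing about robustness. The shared part of the wild-type and double-knockout lists was 57.8% and 70.9% when 50% of both peaks had to overlap (wild-type-only share of library-only peaks 64.0%), 62.0% and 76.1% with centres within 200 bp (66.1%), 67.3% and 83.6% with gaps of up to 500 bp (71.0%), 61.2% and 75.1% in the upper 50% of both lists (16638 and 8704 library-only peaks), 79.6% and 85.3% for each upper 50% against the whole other list (63.0%, 8753 and 5131 peaks), 68.6% in both at equal list lengths (50% by construction, 21980 peaks each), 61.9% and 76.0% with peaks recentred to 200 bp (66.1%), and 61.8% and 77.4% with peaks within 500 bp merged (68.0%). With gaps of up to 500 bp the double-knockout-only count fell to 11465. In 2 alternatives added after the data were seen, the strongest 10% of peaks had 93.4% and 93.8% shared (56.5%, 567 and 436 peaks), and gaps of up to 5 kb gave 77.6% and 91.4% (76.3%, 19254 and 5980 peaks). Limiting the lists to autosomes changed none of these beyond its interval. Chromosome 13 stayed above chromosome 11 in its wild-type-only share except in the strongest 10% (53.3% against 56.9%). Those shares rest on only 45 and 51 library-only peaks and were given no interval, so they do not establish a reversal. At equal list lengths chromosome 11 turned towards the double knockout (53.7% on chromosome 13 against 44.7%). The largest wild-type window excess was on chromosome 14 under every window setting, at 10 in 100 kb, 34 in 500 kb and 80 in 2 Mb windows. It was reached by 3483 of 10000 reassignments as planned, by 79 of 1000 with gaps of up to 500 bp, by 16 with shifted windows, by 3 at equal list lengths and by 999 in 100 kb windows. The largest double-knockout excess stayed on the X array except in 2 Mb windows (39, on chromosome 12) and without the sex chromosomes (11, on chromosome 12, reached by 29 of 1000 reassignments). The planned counts by gene location, at listed genes and of motifs were not run, as they need an mm9 annotation or sequence.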

Other observations

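The tests of the Y and X peaks, of the strong library-only peaks and of the scores on chromosome 14 were chosen after the results were seen, as were the 2 Mb windows, the limit to autosomes and the use of the window reassignments as a test of random spread, while the other window settings were planned. The limits behind the isolated X peaks and the chromosome 14 stretch were chosen after other limits had been tried.

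The wild-type list had 10 Y peaks, the strongest with a score of 35.5 at 346930 to 347080, and the double-knockout list had none, while the X held 17 of the 21 isolated strong double-knockout-only peaks. Peaks missed at random do not account for the 3 strongest Y peaks, since only 1.19% (interval 0.993 to 1.41%) of the 10765 wild-type peaks elsewhere with scores of at least 23.9 lacked a double-knockout peak within 500 bp. Embryos of different sex in the 2 libraries are a candidate explanation, because an inactive X is known to keep a few accessible sites. The X share of isolated double-knockout-only peaks was looked at outside the X array, and it depended on the cut. The cut tried first (strongest 10%, 1 kb) put 11.1% of 9 such peaks on the X (0.281 to 48.2%), against 2.42% of all double-knockout peaks. The cut used above, chosen afterwards, gave 60.0% of 10 (26.2 to 87.8%), with all 6 X peaks in 1 window of 200 kb. Over the 12 cuts viewed, the interval lay above 1.5 times the X share of all peaks in 5 and below it in 1. The strongest 10% with 5 kb or 10 kb left 1 peak outside the array, too few for an interval above that limit. These shares could not decide on sex, because the array, which held most of the 17 isolated X peaks, was left out. A few accessible sites also need not raise the X share at loose cuts. These shares therefore leave sex open. The Y peaks do not depend on these cuts. The wild-type list held 10, of which 3 had scores of at least 23.9, and the double-knockout list held none. A difference in sex would give this pattern, and peaks missed at random do not account for those 3. The sex of the embryos is not given in the sources used here. The genotype itself cannot be told apart from sex, because there is 1 library per combination of genotype and Y peaks. The YFP gate differs as well.

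Of the 1003 library-only peaks in the strongest 10% of the lists, 90.8% (88.9 to 92.5%) had a peak of the other list within 500 bp, against 6.05% of the peaks of the strongest 10% that no longer overlapped the other list after a move by 10 kb. This is consistent with 1 accessible region being called at different positions in the 2 lists, which the fixed width allows. The move shows only that this closeness is above background. It cannot separate 1 region called at different positions from separate neighbouring sites. A change in the position of accessibility within such regions was not tested.

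The wild-type-only peaks of the chromosome 14 stretch had a median score of 7.56. This was above the 4.71 to 5.91 spanned by 95% of the medians of equally many random wild-type-only peaks. They were thus stronger than wild-type-only peaks in general. Their median still lay below the 7.99 of the whole wild-type list and the 10.7 of its shared peaks. Weak peaks missed in the double knockout are therefore not excluded. Labels spread at random reached the 500 kb excess in 3 of 1000 reassignments; multiplied by the 6 planned window settings this is 1.8%. The other settings ranged widely, from 0 of 1000 in 2 Mb windows (excess 80, highest random excess 71), 3 of 1000 at equal list lengths and 16 with shifted windows to 79 with gaps of 500 bp counted as shared, 3483 of 10000 for the 200 kb windows and 999 of 1000 for 100 kb windows, with 311 of 1000 on autosomes alone. Reassignment treats neighbouring peaks as independent, so these shares are too small if accessibility changes over whole domains. A difference in copy number between the animals, or a change that follows the loss of E2A and HEB, was not tested and stays open.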
